A study of Mus musculus with 3 samples.

How the data were processed

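Natural killer (NK) cells, innate lymphocytes that kill tumor cells, were sorted from the lungs of Albino B6 mice that had received Lewis lung carcinoma (LLC) cells, a mouse lung tumor line, by injection into the lung. Per the labels, the sorted cells were alive, carried CD45 and NK1.1 and lacked CD3, and antibodies against CD11b and CD27 were part of the same stain. Each of the 3 libraries was made with the 10x Genomics Chromium single-cell 3' chemistry, in which every captured transcript receives a unique molecular identifier (UMI). The targeted number of cells was 10000 per condition. The libraries came from the non-tumoral part of the lung, from a small tumor and from a large tumor, with 1 library per group.

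The deposited matrices hold UMI counts per gene and barcode with no normalization, for 31053 genes and all 6794880 barcodes of the kit. The values were checked to be whole numbers. The genome build was mm10 and the software Seurat, per the submitters' processing notes, which give no version for either. The aligner, the counter and the gene annotation are not given in the sources used here. Seurat results of the authors were not used here. Because the matrices were unfiltered, cells were called anew, and the calls can differ from those of the authors. Gene positions were taken from the GENCODE M21 annotation of mm10, which matched 30934 of the 31053 gene identifiers.

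A barcode was called a cell with at least 500 UMIs, at least 250 detected genes and at most 10% mitochondrial UMIs, with the same limits in every library. The cells with the highest doublet scores were then removed, at 0.8% of cells per 1000 cells called, by an own implementation of Scrublet's nearest-neighbor score. The non-tumoral library held 31643936 UMIs in all and gave 7279 cells after removal of 482 doublets, with 84.5% of the UMIs in cells. The small-tumor library held 28618186 UMIs and gave 5577 cells after removal of 274 doublets, with 87.8% in cells. Only 1224942 UMIs were present in the large-tumor library, which gave 136 cells with no doublet removed and 82.6% of UMIs in cells. Barcodes with 10 to 100 UMIs served as the profile of free RNA, and by the markers of other cell types free RNA was at most 2.72%, 2.19% and 3.99% of the UMIs of NK-like cells in the non-tumoral, small-tumor and large-tumor libraries. No correction for free RNA was made in the values reported, and its subtraction was tried as an alternative.

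Cells of the 3 libraries were clustered together on 2000 variable genes, without mitochondrial, ribosomal and cycling genes, with 30 principal components, 15 neighbors and Leiden resolution 0.5, and without batch correction. A cluster was named for another cell type when at least 2 of its 10 leading genes were markers of that type, and NK-like when at least 3 NK markers were detected with a median above 100 counts per 1000000 UMIs (CPM). The marker lists covered NK, T, B and plasma cells, group 1 and group 2 innate lymphoid cells (ILC1 and ILC2), macrophages or monocytes, neutrophils, dendritic cells, basophils or mast cells, epithelial or tumor cells, endothelial cells, fibroblasts, erythroid cells and platelets. At resolution 0.5 no cluster was named for T cells, plasma cells, ILC2, neutrophils, dendritic cells, basophils or mast cells, epithelial or tumor cells, endothelial cells, fibroblasts, erythroid cells or platelets. The markers were fixed before the counts were read, and these limits were set afterwards. A cluster led by both Cd3 genes and interferon response genes was left unnamed by a rule set after its genes were seen, and at resolution 1.0 it parted into a T cell-like and an interferon-led NK-like cluster. NK-like cells were compared, and the other classes were left out of the comparisons.

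For each library the UMIs of all NK-like cells were summed and expressed as CPM with exact 95% Poisson intervals. The ratio of 2 libraries was given its exact conditional (Clopper-Pearson) 95% interval. A gene counted as higher or lower when the bound of its interval nearest to 1 was at least 2-fold and its higher library had at least 10 CPM, and ribosomal and mitochondrial genes were counted apart. These intervals, and the exact binomial (Clopper-Pearson) intervals of shares of cells, cover counting error only. No test and no p-value was made, because each group had 1 library and cells of the same library are not independent replicates. The rule was tested on simulated Poisson counts for 31053 genes, 200 of them with a known difference. Those 200 were drawn from genes of at least 50 CPM in the 2 libraries pooled, so recovery between 10 and 50 CPM was not measured. The rule called 0, 1 and 2 of the genes without a difference in the comparisons of small tumor with lung, large tumor with lung and large with small tumor. It recovered 100%, 98.0% and 100% of 3-fold differences, 100%, 82.0% and 82.0% of 4-fold lower genes and 0% of 1.5-fold differences. Such counts follow the model of the intervals and hold no clumping of UMIs in single cells. The simulation therefore gives no rate of false calls for the real libraries.

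Gene lists, the limits for cells and the rules for comparing libraries were fixed before the counts were read. They covered the mature (CD11b-high) and immature (CD27-high) stages of NK cells, cytotoxic machinery, cytokines and chemokines, activating and inhibitory receptors, NK transcription factors, ILC1 and tissue residency, the TGF-beta and type I interferon responses, proliferation, dissociation and heat shock, hypoxia and glycolysis, oxidative phosphorylation, trafficking receptors, activation and cytokine receptors, endoplasmic reticulum (ER) stress, lipid metabolism and ribosomal proteins. A list was described by its members with at least 10 CPM in any library, through the median of log2 ratios with 5 CPM added to both libraries and an order-statistic 95% interval over members, called the member interval. The percentile of that median among 10000 random lists of the same size, matched on expression in 20 bins, describes these libraries and is not a p-value. A list member counted as higher or lower when its ratio interval excluded 1. Shares of cells with a UMI of a gene were taken after every cell was thinned to 1000 UMIs, with shallower cells left out. For a gene found in 0 cells, the share printed as allowed is that of 3 cells.

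The genes named were chosen by a rule fixed in advance. They were the 10 genes above and the 10 genes below a ratio of 1 whose interval lay farthest from 1 among genes with at least 50 CPM in the higher library, whether or not they passed the 2-fold rule, without ribosomal, mitochondrial, antigen receptor and hemoglobin genes and unnamed models. To these were added up to 4 members of each list with the largest ratios whose interval excluded 1, and Itgam, Cd27, Klrg1, Gzma, Gzmb, Prf1, Ifng, Tbx21, Eomes and Ncr1. Further list members are named where they complete a count, and the result of 1 gene is not reported. Alternatives covered the cell limits, doublets, clustering, the cells compared, the scaling, free RNA, depth, the pseudocount and the expression minimum, and 3 of them were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.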

Results

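Single-cell RNA counts were examined for sorted NK cells from the non-tumoral part of LLC-bearing lungs, from a small tumor and from a large tumor, with 1 library per group. Per the series description, lungs of mice with small or large tumors were parted into tumoral and non-tumoral tissue, and the series title places the question at the maturation and the cytotoxic functions of NK cells at different tumor stages. With 1 library in each group, nothing separates the condition from the library or the animal, and the labels do not say how many mice contributed to a library. Nor do they say whether the non-tumoral library came from mice with small or with large tumors. The libraries differed in depth. The non-tumoral library had 31643936 UMIs and 7279 cells with a median of 3329 UMIs and 1665 genes, and the small-tumor library had 28618186 UMIs and 5577 cells with a median of 3929 UMIs and 1872 genes. The large-tumor library had 1224942 UMIs and 136 cells with a median of 6462 UMIs, so its values rest on far fewer cells.

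NK-like cells formed most of each sorted library, but their share was lower in the tumor libraries. They made up 94.9% of called cells in the non-tumoral lung (6906 of 7279, 95% interval 94.3 to 95.4), 86.3% in the small tumor (4815 of 5577, 85.4 to 87.2) and 62.5% in the large tumor (85 of 136, 53.8 to 70.6). B cell-like cells, led by Cd79a, Ebf1 and Ms4a1, made up 1.18% of cells in the lung, 6.51% in the small tumor and 18.4% in the large tumor. ILC1-like cells, marked by Tmem176b, Cxcr6 and Il7r, made up 2.10%, 3.71% and 4.41% in the same order. Macrophage or monocyte-like cells with Lyz2, C1qa and Il1b made up 0.879%, 0.968% and 7.35%. With at least 1000 UMIs and 500 genes per cell these were 0.421%, 0.487% and 3.88%. A mixed cluster led by Cd3e, Cd3d and interferon response genes such as Ifit3 made up 0.962%, 2.47% and 7.35%.

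**Figure D1:**
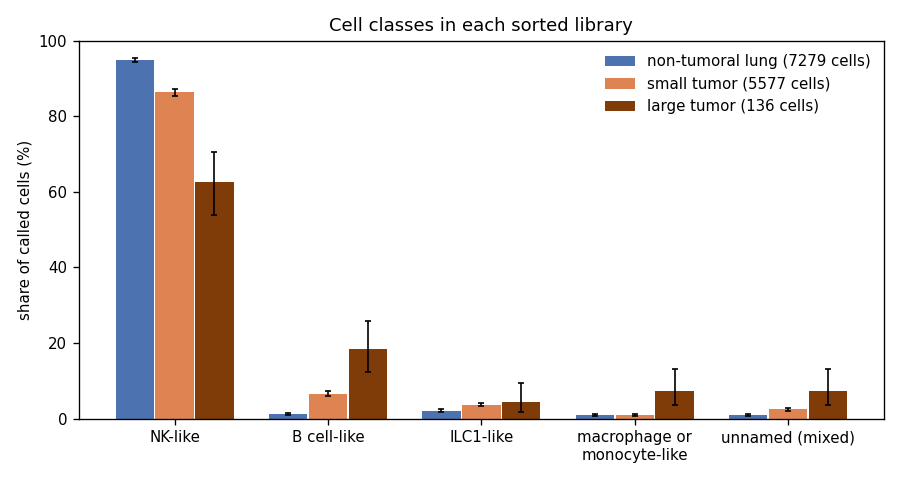
Share of called cells (%) in each cell class for the 3 sorted libraries, with bars for the share and error bars for the exact binomial 95% interval, which covers counting error only. NK-like cells were 94.9%, 86.3% and 62.5% of cells in the non-tumoral lung, the small tumor and the large tumor, and B cell-like cells were 1.18%, 6.51% and 18.4%.

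The gates on CD3 and NK1.1 and the depth of a library can set these shares. NK-like cells pooled 7 clusters, and the 3 largest in the lung were not the same as the 3 largest in the tumors. In the non-tumoral lung the largest were led by Ly6c2 and Cma1 (24.7% of called cells), by Frmd5 and Cnnm2 (22.5%) and by Kcnj8 and Cdc20b (20.4%). In the small tumor they were led by Frmd5 and Cnnm2 (25.8%), by Crtam and Xcl1 (22.0%) and by Kcnj8 and Cdc20b (18.8%), and in the large tumor by Crtam and Xcl1 (21.3%), Kcnj8 and Cdc20b (13.2%) and Frmd5 and Cnnm2 (12.5%). Heat shock genes led a further NK-like cluster (Hspa1b, Hspa1a and Jun), which held 15.5% of called cells in the lung, 4.30% in the small tumor and 9.56% in the large tumor, and cycling genes another (Hist1h1b, Pclaf and Mki67). Several leading genes of these clusters differ between the libraries below, so the cluster sizes are given only to name the cells compared.

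The comparison of the small tumor with the non-tumoral lung asked how NK-like cells at an early tumor stage differ from those in the non-tumoral part of the lung. NK-like cells of the small tumor had higher levels of Cd83, Crtam, Xcl1 and most TGF-beta response genes and lower levels of most genes of mature NK cells. Cd83, an activation-induced surface glycoprotein, was 4.90 times as high in the small tumor (53.5 against 10.9 CPM, interval of the ratio 4.29 to 5.61). Crtam, an adhesion receptor of activated lymphocytes, was 4.37 times as high (98.3 against 22.5 CPM, 3.98 to 4.81), and Xcl1, a chemokine that attracts cross-presenting dendritic cells, was 3.13 times as high (620.01 against 198.1 CPM, 3.03 to 3.23). Ly6c2, a surface protein of late-stage NK cells, had a ratio of 0.431 (274 against 635 CPM, 0.418 to 0.445), and Txnip, an inhibitor of glucose uptake, had a ratio of 0.377 (134 against 356 CPM, 0.361 to 0.394).

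By the 2-fold rule, 30 of 8227 genes tested were higher and 9 were lower in the small tumor, with a median log2 ratio over all genes of -0.01. The higher genes named by the rule also included Serpine2, a secreted protease inhibitor (ratio 3.33), Pmepa1, a TGF-beta-induced inhibitor of SMAD signaling (3.20), Mir155hg, the host transcript of an immune microRNA (interval 2.82 to 3.41), Ikzf2, which encodes the transcription factor Helios (2.97), the kinase gene Pak1 (2.87), Il21r (2.59) and Mpp7 (2.29). Among lower genes of at least 50 CPM, Tex14 (0.366), Prdm1, which encodes the transcription factor Blimp-1 (0.427), Txnip and Ly6c2 passed that rule. The next 6 did not pass it, since the bound of their interval was less than 2-fold from 1. These were Rhob (0.466), Jun (0.482), Ifitm10 (0.495), S100a4 (0.505), Hspa1b, an inducible heat shock gene (0.506), and Lgals1, which encodes galectin-1 (0.523). Of these 10 genes, 6 were also among the 10 leading genes of the heat shock cluster. Without it, a setting added after the data were seen, the log2 ratios were 0.76 for Hspa1b, -0.16 for Jun, -0.54 for Rhob, -0.95 for Prdm1, -1.08 for Txnip and -1.17 for Tex14. In the annotation of mm10, Cd83 (ENSMUSG00000015396) lies on chromosome 13 from 43784775 to 43803132, Crtam (ENSMUSG00000032021) on chromosome 9 from 40969691 to 41004628, Xcl1 (ENSMUSG00000026573) on chromosome 1 from 164931644 to 164935527 and Ly6c2 (ENSMUSG00000022584) on chromosome 15 from 75108158 to 75111970. UMIs were counted per whole gene, so no exon or transcript can be assigned to these values.

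Genes of the mature, CD11b-high stage of NK cells were lower as a group in the small tumor. The median log2 ratio of the 12 measured members was -0.59 (member interval -0.80 to -0.12, percentile 0.0 among random lists), with 11 members lower and S1pr1 higher at a ratio of 1.39. Read in other classes after the data were seen, the list had a median of -1.21 in B cell-like cells (member interval -2.51 to 0.02), -0.92 in ILC1-like cells (-1.39 to 0.22) and 0.05 in macrophage or monocyte-like cells, and both intervals included 0. The B cell-like value cannot be read as a change in B cells. Those cells carried NK RNA, and more of it in the lung than in the small tumor (1003.7 against 172 CPM of Gzma). Beside Ly6c2 and Prdm1, the lower members included S1pr5, a sphingosine-1-phosphate receptor used to leave tissues (0.555), Klf2, a transcription factor of lymphocyte trafficking (0.572), and Klrg1, an inhibitory receptor of mature NK cells (0.578, 124 against 214 CPM). Among the 12 members of the immature, CD27-high list, 7 were higher, Cd7 was lower at 0.936 and 4 had intervals that included 1, with a median of 0.21 (member interval -0.07 to 0.46, percentile 99.8). Cd27 itself, a costimulatory receptor of the earlier stages, had 167.3 CPM in the small tumor and 79.4 CPM in the lung (ratio 2.11, 1.99 to 2.23). The transcription factor gene Tcf7 had a ratio of 1.95 at low counts of 134 and 82 UMIs.

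Cytotoxic and receptor genes were mostly lower in the small tumor. Of the 17 measured members of the cytotoxic list, 11 were lower and 6 higher, with a median of -0.16 (percentile 0.44). Gzma, the most abundant granzyme transcript, had 10271 CPM in the small tumor and 14220.4 CPM in the lung (ratio 0.722), the pore-forming protein gene Prf1 had a ratio of 0.775, Gzmb of 0.842 and Rab27a, which acts in granule release, of 0.679. Gzmk (1.86) and Gzmc (1.67) were higher. Activating receptors and adaptors had a median of -0.30 (percentile 0.0), and 14 of 15 members were lower, among them Ncr1, which encodes NKp46 (ratio 0.607), Cd244 (0.644) and Klrb1c, which encodes the NK1.1 antigen of the sort (0.649); Crtam was the exception. Inhibitory receptors and checkpoints had a median of -0.36 (percentile 0.0), with 11 of 12 members lower, among them Lair1 (0.601), Klra1 (0.722) and Klra3 (0.753), and Ctla4 higher at 1.20.

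TGF-beta response genes showed the highest list median. It was 0.72 (member interval 0.369 to 0.999, percentile 100), with 8 of 9 members higher and Cd9 lower at 0.959. Beside Pmepa1, these were led by Tgfb1, the gene of the cytokine itself (ratio 2.02, 595.1 against 295.2 CPM), the inhibitory SMAD gene Smad7 (1.81) and the corepressor gene Skil (1.78). The same list, read in other classes after the data were seen, had a median of 0.44 in B cell-like cells (member interval 0.40 to 0.61), 0.19 in ILC1-like and -0.03 in macrophage or monocyte-like cells. The cytokine list had a median of 0.27 (percentile 99.7), with 6 of 8 members higher. Csf2, which encodes GM-CSF, had a ratio of 3.86 (485 against 150 UMIs), with 265 of the small-tumor UMIs in 1 cell, and turned to a log2 ratio of -0.47 without cells holding a T cell receptor complex UMI. Ccl3 (0.649) and Ccl5 (0.901) were lower, and Ifng was 1.15 times as high, a direction that turned when every cell was thinned to the same depth or given equal weight. Type I interferon response genes had a median of 0.25 (percentile 99.9), with 7 of 10 members higher, Bst2 at 1.70 and Irf7 at 1.41 among them, and Zbp1 lower at 0.881. The mixed cluster, led in part by interferon genes, was left out of this median, with 70 lung and 138 small-tumor cells. At resolution 1.0 an interferon-led NK-like cluster held 16 lung and 82 small-tumor cells, so cells high in these genes were left out unequally.

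Proliferation genes had a median of -0.30 (percentile 0.0), and 12 of 14 members were lower, including Birc5 (0.549), Hmgb2 (0.653), Pclaf (0.667) and Mcm5 (0.695), with none higher. The NK transcription factors had a median of 0.06 (percentile 61.9) with 7 members higher, 5 lower and Tox at 1.04 with an interval that included 1. Runx3 was higher at 1.48, Id2 was lower at 0.767, and the master regulators Tbx21 and Eomes had ratios of 0.922 and 1.08, the latter with a log2 ratio of -0.03 when all called cells were summed. Activation and cytokine receptors had a median of 0.07 (percentile 75.9), with Il2ra, the high-affinity interleukin-2 receptor chain, at 4.93 (326 against 79 UMIs), Nr4a3 at 1.84 and Tnfrsf9 at 1.43. Trafficking receptors had a median of -0.15 (percentile 1.12), with Cx3cr1 at 0.602 and the lymph node homing receptor gene Ccr7 at 3.75. The ILC1 and residency list had a median of 0.02 (percentile 55.0), with Il21r, Inpp4b (2.45) and Itgb3 (1.54) higher and Rgs1 (0.732), Rgs2 (0.876) and Cd69 (0.926) lower.

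Stress and metabolic genes went both ways. The hypoxia and glycolysis list had a median of 0.13 (percentile 96.7), with Vegfa at 1.47, P4ha1 at 1.44 and Ldha at 1.35. Dissociation and heat shock genes had a median of 0.02 (percentile 41.9) over members that went both ways, with Hspa8 at 1.73 and Fos at 0.647. The medians were -0.08 for oxidative phosphorylation (percentile 6.78), where Cycs was at 1.30 and Atp5b at 0.818, and -0.18 for ER stress (percentile 1.01), where Dnajb9 was at 0.746. They were 0.03 for lipid metabolism (percentile 70.9), with Fabp5 at 1.90 and Srebf1 at 0.711, and 0.05 for ribosomal proteins (percentile 83.6).

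The share of NK-like cells with a Cd27 UMI, at 1000 UMIs per cell, was 5.67% in the non-tumoral lung (384 of 6771, 5.13 to 6.25) and 11.7% in the small tumor (560 of 4796, 10.8 to 12.6). It was 15.7% in the large tumor (13 of 83, 8.61 to 25.3), whose interval overlapped that of the small tumor. At that depth 135, 19 and 2 cells of the lung, the small tumor and the large tumor were left out as too shallow. With all UMIs and all cells kept the share was 16.0%, 31.7% and 41.2% in the same order. In B cell-like cells at the same depth Cd27 was found in 2 of 83 cells in the lung (2.41%), 4 of 363 in the small tumor and 1 of 24 in the large tumor (4.17%). The median depths before thinning of NK-like and B cell-like cells were 3307 and 3349.5 UMIs in the lung, 3854 and 4170 in the small tumor and 6139 and 6978 in the large tumor. Itgam, which encodes CD11b, gave 1 of 6771 cells in the lung, 0 of 4796 in the small tumor, which allows a share of up to 0.063%, and 0 of 83 in the large tumor, which allows 3.61%. Itgam UMIs were near 0 in all barcodes of the 3 libraries, with 3 in all, so the CD11b stage could not be read from its own transcript. The count of 30 higher genes in the small tumor was 12 with cells thinned to 1000 UMIs, 10 of them among the 30. It was 6 without cells holding a T cell receptor complex UMI, 3 of them among the 30. That setting kept 1460 of 4815 small-tumor cells and 2413 of 6906 lung cells. CD11b and CD27 antibodies in the sort can set the shares of the maturation stages.

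**Figure D2:**
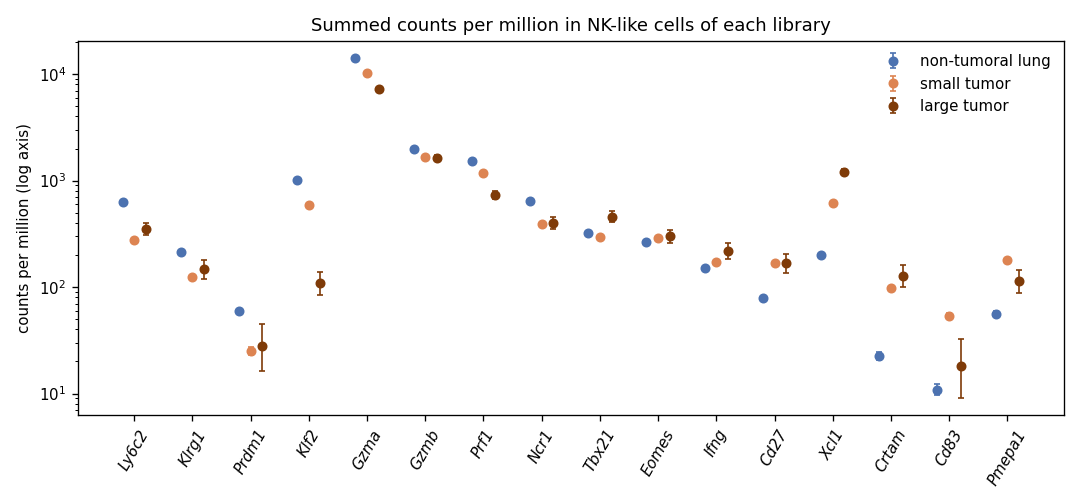
Summed counts per 1000000 UMIs (log axis) of 16 genes in NK-like cells of the 3 libraries, with points for the value and error bars for the exact Poisson 95% interval, which covers counting error only and is often smaller than the point. Ly6c2, Klrg1, Gzma and Ncr1 were lower in both tumor libraries than in the non-tumoral lung, and Cd27, Xcl1 and Crtam were higher.

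The comparison of the large tumor with the non-tumoral lung asked the same question at a later tumor stage, over 85 NK-like cells and 610529 UMIs in the large tumor. Xcl1 and Cd27 were higher in the large tumor, and Prf1, Gzma and Klf2 were lower. Xcl1 was 6.09 times as high (1207 against 198.1 CPM, 5.63 to 6.59), with UMIs in 54 of the 85 cells, and Cd27 was 2.10 times as high (167.1 against 79.4 CPM, 1.71 to 2.57). Prf1 had a ratio of 0.478 (732 against 1532 CPM, 0.434 to 0.524) and Gzma a ratio of 0.512 (7287 against 14220.4 CPM, 0.497 to 0.528). Klf2 had a ratio of 0.107 (110 against 1021 CPM, 0.0832 to 0.137), and in B cell-like cells of the same libraries, in which it is also a trafficking factor, its ratio was 0.124.

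By the 2-fold rule, 125 genes were higher and 183 lower in the large tumor, apart from 15 ribosomal or mitochondrial genes that were higher, and the median log2 ratio over all genes was -0.14. Many of the higher genes rested on few cells. UMIs lay in fewer than 10 of the 85 cells for 50 of the 125, and 1 cell held at least 50% of the UMIs for 21. All 36 Dqx1 UMIs (ratio 61.7) came from 1 cell, and 65 of the 78 UMIs of Gzmc, which encodes granzyme C (ratio 31.2), came from 1 cell. Dscam (18.9) had UMIs in 9 cells, with 29 of 94 in 1 cell. Dscam and Gzmc were also among the 10 leading genes of the ILC1-like cluster that was left out. Further genes of the higher side were the semaphorin gene Sema3c (16.8), Rgs16, a regulator of G-protein signaling (9.07), Plac8 (6.79), Spp1, which encodes osteopontin (6.28), the anti-apoptotic gene Bcl2a1d (5.65) and Kalrn (5.03, with UMIs in 78 cells). Without cells holding a T cell receptor complex UMI, which left 16 large-tumor cells, the log2 ratio of Spp1 was -0.73. The lower side was led by Scand1 (0.0410), Klf2, Cebpb, which encodes a stress-responsive transcription factor (0.0975), Klhdc2 (0.125), Ppp1r14b (0.101), Taf10 (0.143), Marc2 (0.110), Tprgl (0.151), Tmem55b (0.0810) and Frat2 (0.0821). Klf2 (ENSMUSG00000055148) lies on chromosome 8 from 72319033 to 72321656, and Prf1 (ENSMUSG00000037202) on chromosome 10 from 61297833 to 61304680.

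Several of these ratios recurred in B cell-like cells of the same libraries, which are another cell type. There the ratio was 0.117 for Scand1, 0.060 for Cebpb, 0.130 for Ppp1r14b, 0.052 for Taf10, 0.114 for Tprgl, 0.254 for Tmem55b, 5.30 for Kalrn and 9.77 for Sema3c. Plac8 was at 1.37 and Marc2 at 0.583 with an interval that included 1. Ribosomal protein genes had a median log2 ratio of 0.60 in NK-like cells (member interval 0.46 to 0.75, percentile 100, 73 of 87 members higher), and 0.42 in B cell-like, 0.75 in ILC1-like and -0.09 in macrophage or monocyte-like cells of the same libraries. These other classes held 25, 6 and 10 cells in the large tumor.

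The immature list had a median of 0.67 in the large tumor against the lung (member interval -0.80 to 1.19, percentile 99.9), with 7 of 12 members higher, Ctla2a (4.29), Tcf7 (3.51) and Thy1 (2.42) among them, and Cd7 lower at 0.501. The mature list had a median of -0.69 (member interval -1.21 to 0.42, percentile 0.06), with 8 members lower. S1pr5 was at 0.208, Cma1, a mast cell protease gene also transcribed in NK cells, at 0.424, and Klrg1 at 0.687, while S1pr1 (1.69), Tbx21 (1.44) and Zeb2 (1.15) were higher. The direction of Klrg1 turned with cells thinned to 1000 UMIs (log2 ratio 0.13), and those of Klrg1 (1.12), Cma1 (0.13) and S1pr1 (-0.55) turned over the 16 large-tumor cells without a T cell receptor complex UMI, where the median of the list was 0.13. The cytotoxic list had a median of -0.38 (percentile 1.12), with 10 of 17 members lower and only Gzmc and Srgn (1.26) higher, and Gzmb had a ratio of 0.837. Lamp1 stood at 0.149, and at 0.196 in B cell-like cells.

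Receptor and cytokine genes followed in part the small-tumor comparison. Activating receptors and adaptors had a median of -0.41 (percentile 0.72), with 10 of 15 members lower, Klrb1c (0.410), Cd226 (0.532) and Ncr1 (0.620) among them, and Crtam higher at 5.68. That median was 0.006 without cells holding a T cell receptor complex UMI. Inhibitory receptors had a median of -0.21 (percentile 14.5), with Klra3 (0.383) and Klra9 (0.490) lowest and Ctla4 at 1.32, a direction that also turned in those 16 cells. Cytokines had a median of 0.57 (percentile 99.1), with 6 of 8 members higher, Tnf (6.70, from 7 and 43 UMIs), Ltb (2.10) and Ifng (1.46) among them, while Ccl5 was at 0.497 and turned to a log2 ratio of 0.17 in those cells. The TGF-beta list had a median of 0.83 (member interval -0.04 to 0.95, percentile 100), with 6 of 9 members higher, Ski at 3.33 and Tgfb1 at 1.81 among them, beside 2.25 and 0.948 in B cell-like cells. Pmepa1 was at 2.01, beside 0.621 in B cell-like cells, and Skil at 1.81, beside 1.51. Without cells holding a T cell receptor complex UMI the log2 ratios of Pmepa1 (-0.49) and Skil (-0.12) turned, and the median of the list was -0.12.

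Transcription factors in the large tumor had a median of 0.20 (percentile 84.7), with Runx3 at 2.36, Nfil3 at 0.322 and Eomes at 1.13, whose interval included 1. Ets1 was at 0.504, and at 0.470 in B cell-like cells. The ILC1 and residency list had a median of 0.39 (percentile 97.6), with Il21r (2.69, beside 1.69 in B cell-like cells) and Inpp4b (2.47, beside 1.33) highest. The activation list had a median of 0.22 (percentile 89.5), with Nr4a3 at 2.48, beside 2.59 in B cell-like cells, and Icos at 0.457. Trafficking receptors had a median of 0.24 (percentile 93.1). Ccr7 was at 4.18, but 14 of its 26 UMIs came from 1 cell and its log2 ratio was -0.10 without cells holding a cycling marker UMI. The interferon list had a median of -0.53 (percentile 3.98), with Irf7 at 0.313 and Isg15 at 0.392. With the mixed cluster included the log2 ratio of Isg15 was 0.14 and the list median 0.56, and that median was also above 0 under 7 other settings. Proliferation genes had a median of 0.03 (percentile 80.4), with H2afz at 0.571 and at 0.435 in B cell-like cells.

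The AP-1 genes Fos and Jun were lower in NK-like and B cell-like cells of the large tumor. Fos had a ratio of 0.251 and Jun of 0.348 in NK-like cells, and 0.183 and 0.119 in B cell-like cells, within a dissociation and heat shock list whose median was -0.09 (percentile 38.9), with 5 members higher and 7 lower. Without the heat shock cluster that median was 0.36. Hypoxia and glycolysis genes had a median of 0.27 (percentile 99.1), with Hk2 at 5.81 and Aldoa at 1.77, the latter beside 2.02 in B cell-like cells, and the median was -0.11 without cells holding a T cell receptor complex UMI. Gapdh, which had few UMIs in any barcode, was at 8.34 from 15 and 74 UMIs. The remaining medians were -0.03 for oxidative phosphorylation (percentile 46.4), -0.19 for ER stress (percentile 32.8), with Xbp1 at 0.402, and 0.18 for lipid metabolism (percentile 92.8), with Acaca at 2.04. The ER stress median was 0.56 without cells holding a T cell receptor complex UMI and 0.26 with cells thinned to 1000 UMIs. Of the counts for this comparison, that of lower genes was 23 with cells thinned to 1000 UMIs, 22 of them in the reported set. Without cells holding a T cell receptor complex UMI it was 12, 8 of them in the reported set. The count of higher genes was 509 over all called cells, 98 of them in the reported set.

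**Figure D3:**
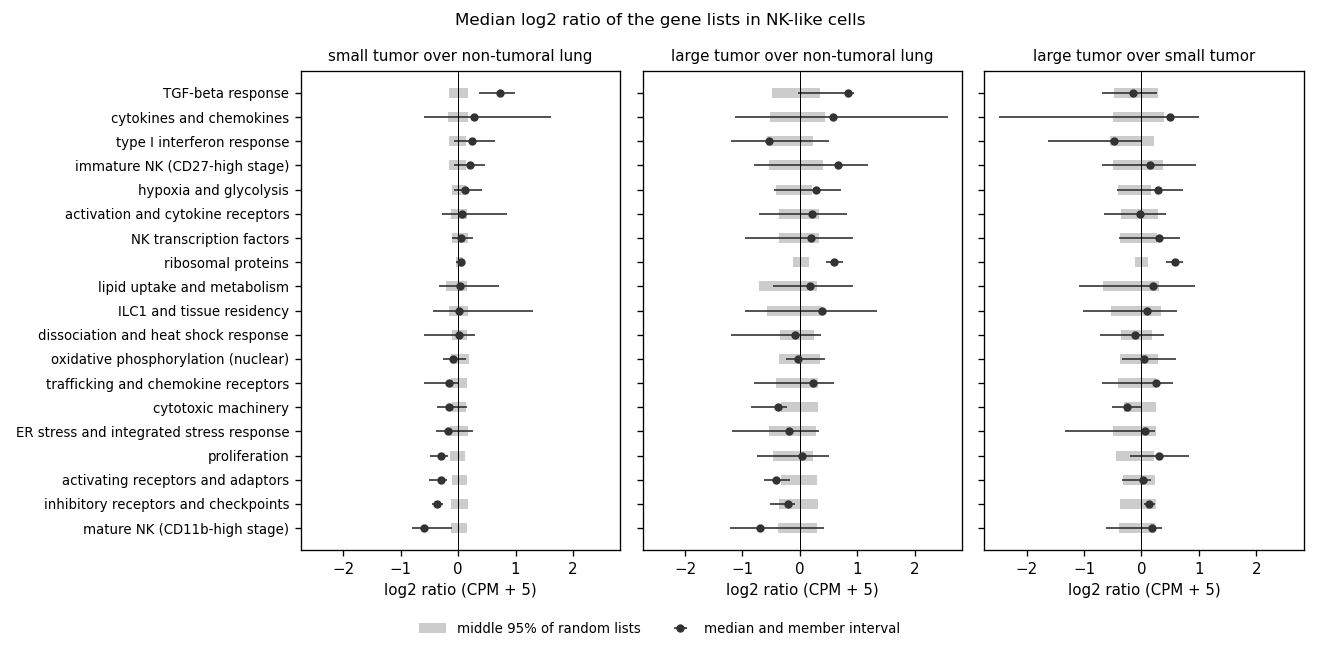
Median log2 ratio (CPM with 5 added) of each gene list in NK-like cells for the 3 comparisons, with points for the median, thin lines for the member interval and gray bars for the middle 95% of random lists of the same size and expression. In the small tumor the TGF-beta response list stood highest at 0.72 and the mature NK list lowest at -0.59, and in the large tumor these lists stood at 0.83 and -0.69 against the non-tumoral lung.

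Comparing the large tumor with the small tumor addressed tumor stage within tumor tissue. Cd27, Eomes and Ncr1 had similar levels in NK-like cells of both tumors, while Prf1 and Gzma were lower and Tbx21 was higher in the large tumor. Cd27 had the same level within counting error in both tumors (167.1 and 167.3 CPM, ratio 0.999, 0.812 to 1.22). The intervals of Klrg1 (ratio 1.19, 0.953 to 1.47), Gzmb (0.994, 0.932 to 1.06), Eomes (1.04, 0.895 to 1.21) and Ncr1 (1.02, 0.895 to 1.16) also included 1. However, 193 of the 1001 Gzmb UMIs and 22 of the 90 Klrg1 UMIs of the large tumor came from 1 cell each. Prf1 was lower in the large tumor (ratio 0.616, 0.560 to 0.677), as was Gzma (0.710, 0.689 to 0.731), and Tbx21, which encodes the transcription factor T-bet, was higher (1.56, 1.38 to 1.76). Ribosomal protein genes had a median log2 ratio of 0.58 (member interval 0.42 to 0.72, percentile 100, 68 of 87 members higher), beside 0.43 in B cell-like, 0.73 in ILC1-like and 0.10 in macrophage or monocyte-like cells.

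By the 2-fold rule, 88 genes were higher and 174 lower in the large than in the small tumor, apart from 16 higher ribosomal or mitochondrial genes, with an all-gene median of -0.12. In B cell-like cells the 94 measured genes of the lower set had a median log2 ratio of -1.69 (member interval -1.92 to -1.46), against -1.80 in NK-like cells. Of the 94, 92 were lower in B cell-like cells. No median over all genes of that class was set beside these values. The 24 measured genes of the higher set had a median of 1.16 in B cell-like cells, and 22 of them were higher. A gene could be measured there through its level in the large tumor alone, which favors that direction. The lower genes named by the rule were Cebpb (0.0773), Scand1 (0.0517), the AP-1 gene Jund (0.161), Ppp1r14b (0.0883), Pnrc1 (0.178), Klhdc2 (0.127), Marc2 (0.108), Frat2 (0.0778), Tmem55b (0.0782) and Klf2 (0.188). In B cell-like cells Jund was at 0.270, Pnrc1 at 0.201, Klf2 at 0.203 and Tmem55b at 0.233. The higher genes were Dqx1 (77.5, all from 1 cell), Sema3c (33.8), Gzmc (18.7, 83.3% from 1 cell), Kalrn (5.42) and Dscam (5.15, with UMIs in 9 cells). They also included Cfap77 (4.74), Rgs16 (4.48), the calcium-binding protein gene S100a4 (4.46), Ier3ip1 (3.91) and Spp1 (3.27). In B cell-like cells Sema3c was at 26.8, Kalrn at 5.64 and S100a4 at 31.6, and the log2 ratios of Ier3ip1 (-0.32) and Spp1 (-0.73) turned without cells holding a T cell receptor complex UMI.

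**Figure D4:**
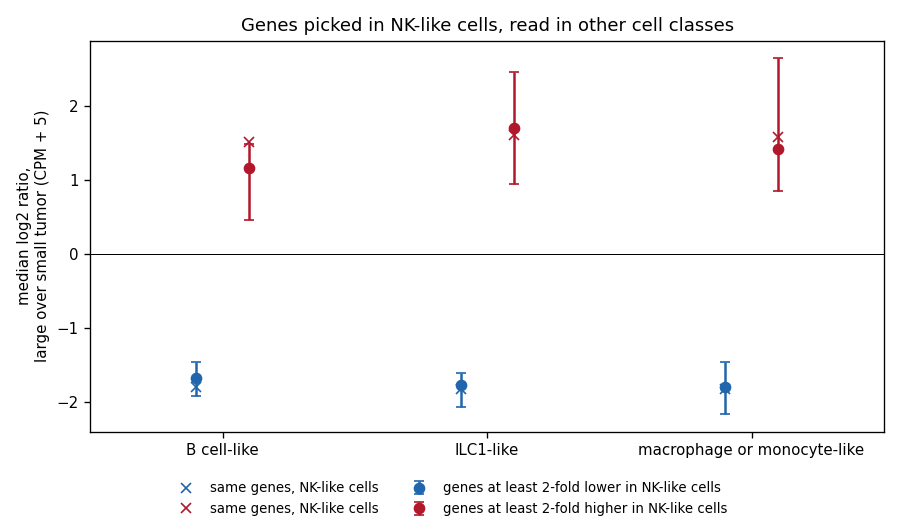
Median log2 ratio (CPM with 5 added) of large over small tumor in 3 other cell classes for the genes at least 2-fold lower (blue) or higher (red) in NK-like cells, with circles for the class, error bars for the member interval and crosses for the same genes in NK-like cells. Lower genes stood at -1.69, -1.78 and -1.80 in B cell-like, ILC1-like and macrophage or monocyte-like cells, of which the large-tumor library held 25, 6 and 10.

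Of the lists, immature genes had a median of 0.14 (percentile 84.0) in the large against the small tumor, with Ctla2a (3.19), Thy1 (2.04) and Xcl1 (1.95) higher, Cd7 (0.535) lower and the other 8 members with intervals that included 1. The mature list had a median of 0.18 (percentile 95.1) with 4 members higher (Cx3cr1 2.31, Tbx21 1.56, Ly6c2 1.28, Zeb2 1.24) and 4 lower (Gzma 0.710, Cma1 0.641, S1pr5 0.375, Klf2 0.188), and its median was -0.13 with cells thinned to 1000 UMIs and 0.77 without cells holding a T cell receptor complex UMI, where the immature median was -0.50. For Cx3cr1, 13 of the 24 UMIs came from 1 cell, and its log2 ratio was -0.78 with cells thinned to 1000 UMIs. Cytotoxic genes had a median of -0.24 (percentile 6.91) with 8 of 17 members lower, Lamp1 at 0.165 among them and at 0.163 in B cell-like cells, and Gzmc and Srgn (1.12) higher. The cytokine list had a median of 0.49 (percentile 99.2), with Tnf at 3.30, Ccl3 at 2.03 and Ifng at 1.27, and Csf2 gave 0 UMIs in the large tumor against 485 in the small tumor, 265 of them in 1 cell.

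Activating receptors had a median of 0.03 (percentile 70.7), with Cd244 at 1.46, Klrb1c at 0.631 and Fcer1g at 0.738. The log2 ratio of Klrb1c was 0.02 with thinned cells. Inhibitory receptors had a median of 0.14 (percentile 89.3), which turned to -0.21 over all called cells and to -0.39 without cells holding a T cell receptor complex UMI. Transcription factors had a median of 0.31 (percentile 98.3), with Id2 at 1.72, Nfil3 at 0.267 and Ets1 at 0.487, the last beside 0.522 in B cell-like cells. TGF-beta response genes had a median of -0.15 (percentile 28.4), with Ski at 2.18, Pmepa1 at 0.629 and Smad7 at 0.613, beside 1.63, 0.454 and 0.184 in B cell-like cells. Interferon genes had a median of -0.48 (percentile 4.67), with Irf7 at 0.223 and at 0.318 in B cell-like cells, and the median turned to 0.14 with the mixed cluster included. Proliferation genes had a median of 0.31 (percentile 99.4), which was -0.31 without cells holding a cycling marker UMI, and 23 of the 26 UMIs of Pclaf (1.95) and 14 of the 19 UMIs of Rrm2 (2.25) came from 1 cell each.

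Further medians were 0.29 for hypoxia and glycolysis (percentile 99.7), with Hk2 at 2.70, Ero1l at 0.295 and a median of -0.30 without cells holding a T cell receptor complex UMI, 0.25 for trafficking receptors (percentile 97.2) and 0.20 for lipid metabolism (percentile 92.7), with Fabp5 at 0.356. They were 0.09 for ILC1 and residency genes (percentile 78.6), with Cd69 at 1.56 and Rgs1 at 1.53, 0.07 for ER stress (percentile 83.0), 0.04 for oxidative phosphorylation (percentile 68.1), -0.02 for activation and cytokine receptors (percentile 55.9) and -0.11 for dissociation and heat shock genes (percentile 36.5). The heat shock median was 0.52 without cells holding a T cell receptor complex UMI. The count of lower genes was 25 both with cells thinned to 1000 UMIs and without cells holding a T cell receptor complex UMI. Of these, 22 and 16 were in the reported set. The count of higher genes was 52 with thinned cells and 354 over all called cells, but only 23 and 63 of them were in the reported set.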

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

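The tests of depth per cell, of the sort antibodies and of annotated genes at Itgam and Irf8 were chosen only after the result was seen. Cells of classes that the comparisons left out were present in libraries sorted for NK1.1 and against CD3. B cell-like cells made up 1.181% of called cells in the non-tumoral lung, 6.509% in the small tumor and 18.382% in the large tumor. ILC1-like cells, which carry NK1.1 and so pass the gate, made up 2.102% in the lung and 3.712% in the small tumor. Macrophage or monocyte-like cells made up 0.879%, 0.968% and 7.353% in the 3 libraries, and 0.421%, 0.487% and 3.876% with at least 1000 UMIs and 500 genes. In the large tumor their median depth was 1688 UMIs, beside 6139 in NK-like cells, so many of them were shallow barcodes.

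Genes that differed in NK-like cells between the large and the small tumor also differed in the other cell classes, of which macrophage or monocyte-like cells held NK RNA (5316 CPM of Gzma in the small tumor, beside 172 CPM in B cell-like cells) and are not separate evidence. Of the 174 lower genes, the 94 measured in B cell-like cells (at least 50 CPM in either library) had a median log2 ratio of -1.685. It was -1.776 for the 120 measured in ILC1-like cells and -1.801 for the 123 measured in macrophage or monocyte-like cells. Those classes held only 6 and 10 large-tumor cells with 61649 and 50021 UMIs, where 50 CPM is few UMIs. The B cell-like value, from 25 large-tumor cells, could also follow from a difference of the whole library that acts on every cell type. After GC correction 71.8% of the lower genes stayed at least 2-fold lower, between the bounds set at 50% and 80%. The median log2 ratio over all genes was -0.067 in the lowest and -0.301 in the highest GC bin, beside -1.80 for the 94 lower genes measured above. These values argue against GC content as the source of most of that fold. For calls near the 2-fold bound, GC content cannot be told apart from other causes. A single cell held at least 50% of the UMIs for 19.3% of the 88 higher genes (17 genes, Dqx1 and Gzmc among them), between the bounds set at 10% and 50%. UMIs lay in fewer than 10 cells for 35 of the 88, and in a median of 14.5 cells over the set. Single cells stay open as an explanation of part of the set. Of the 24 higher genes measured in B cell-like cells, 22 were higher there too. A gene could enter that count through its level in the large tumor alone, so it cannot decide how far single cells account for the set. Tumor size itself stays open and untested, because it falls together with the library.

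Lower mature and higher immature NK genes in the small tumor against the lung were weighed against a mixture of cells, depth and the sort. For ILC1-like cells left among the NK-like cells, the ILC1 markers reached 30.7 CPM, or 6.5% of the 471 CPM that the median mature ratio needs. Clusters led by these markers had been taken out, so a low level was partly set by that step. The value argues only against leftover cells with the marker level of the ILC1-like class, and cells low in these markers stay open. With every cell thinned to 1000 UMIs the mature median was -0.373, so part of it could follow depth per cell, and the remainder cannot be told apart from it by the bounds set. The CD11b and CD27 antibodies of the sort may have set the stages, and the 3 Itgam UMIs in all NK-like cells were too few for a check. The difference between tumor and lung tissue stays open as a biological explanation, and so does a difference of the whole library. The mature list was at -0.921 in ILC1-like cells with a member interval that included 0. Its -1.210 in B cell-like cells, also with an interval that included 0, cannot decide this. Those cells carried more NK RNA in the lung than in the small tumor (1003.7 against 172 CPM of Gzma).

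Itgam gave 3 UMIs and Irf8 0 UMIs over all barcodes of the 3 libraries, and Gapdh 215. Exons of another gene on the same strand covered 0% of the last 500 bases of Itgam and Irf8 and 0% of those of Gapdh. This argues against shared exons within those bases in the annotation used here, and the rest of each gene was not checked. Itgam lies within 99% or more of its length in the span of Gm49368 (chromosome 7, 128062683 to 128128160), and Irf8 in that of Gm20388 (chromosome 8, 119910841 to 124345722). Among protein-coding genes inside such spans 84.0% of 505 had no UMI, against 20.4% of 21392 elsewhere, a ratio of 4.12 that suggests loss of UMIs assigned to overlapping genes as a candidate explanation, and the ratio was 4.86 over the 372 genes wholly inside. The 99% limit was set after the position of Itgam was seen, Gapdh lies in no such span, and no biological explanation was tested.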

How the results depend on the processing

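The settings without the heat shock cluster, with ILC1-like cells and with the mixed cluster were chosen after the data were seen. Under the planned settings 2626 values of named genes kept their direction and stayed within their counting interval, 510 moved beyond it and 36 reversed, and under the added settings these were 653, 86 and 4. For list medians, 897 planned values stayed within the member interval, 16 moved beyond it and 5 reversed from a member interval that excluded 0. Under the added settings these were 159, 2 and 1. A median whose member interval included 0 could change sign without being counted as reversed, and many did. The interferon median of large tumor against lung, for example, went from -0.533 to 0.338 at resolution 1.0. The counts of higher and lower genes, each recomputed under every setting that applies to it, gave 69 planned and 17 added values within 1.5 times the reported count, and 21 and 1 beyond it. No paired analysis was possible because each group had 1 library and the replicate number 1 is shared by all. Depth limits the large tumor most, with 85 NK-like cells and 610529 UMIs. Where nothing else is said, the cause was not tested.

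Over all called cells, the counts of higher and lower genes in the small tumor against the lung were 107 and 14 in place of 30 and 9. Of these, 27 and 9 were in the reported sets. Higher genes in the large tumor were 509 in place of 125 against the lung and 354 in place of 88 against the small tumor. Of these, 98 and 63 were in the reported sets. The log2 ratio of Eomes was -0.03 (small tumor against lung) and of Entpd1 -0.047 (large tumor against lung). Against the small tumor, that of Crtam was -0.031, that of Klra4 -0.21 and the inhibitory receptor median -0.21. Cells of other types enter this sum by construction.

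Without cells holding a T cell receptor complex UMI (Cd3d, Cd3e, Cd3g, Trac, Trbc1 or Trbc2), 2413, 1460 and 16 NK-like cells were left in the lung, the small tumor and the large tumor. These were left of 6906, 4815 and 85, so fewer UMIs widened every interval. NK-like cells held 0, 1 and 0 Cd3e UMIs in these libraries, so nearly all cells left out held another of these transcripts. A turn under this setting therefore does not show T cells among the NK-like cells. Higher genes in the small tumor were 6, only 3 of them in the reported set. The log2 ratios of Csf2, Hk2 and Ifi27l2a were -0.47, -0.35 and -0.17. Against the lung, 12 genes were lower in the large tumor in place of 183, 8 of them in the reported set, and the activating receptor median was 0.006. There the log2 ratios were -0.21 for Atp5b, 0.17 for Ccl5, 0.13 for Cma1, -0.51 for Ctla4, -0.15 for Hspa5, 0.033 for Isg15, 1.12 for Klrg1, -0.49 for Pmepa1, -0.55 for S1pr1, -0.12 for Skil, -0.73 for Spp1, 0.018 for Stmn1 and -0.62 for Tnfrsf9. Against the small tumor, 25 genes were lower in place of 174, 16 of them in the reported set. The medians were -0.39 for inhibitory receptors and 0.77 for mature NK genes. The log2 ratios were -0.827 for Ccr2, 0.63 for Fos, -0.27 for Gata3, -0.32 for Ier3ip1, 1.39 for Il2ra, 0.20 for Klra3 and -0.73 for Spp1.

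With every cell thinned to 1000 UMIs, which widens the intervals, 12 genes were higher in the small tumor, 10 of them in the reported set. The log2 ratio of Ifng was -0.16. In the large tumor 23 genes were lower than in the lung, 22 of them in the reported set, and Klrg1 was at 0.13. Against the small tumor 52 genes were higher and 25 lower, of which 23 and 22 were in the reported sets. Cx3cr1 was at -0.78 and Klrb1c at 0.016. With equal weight per cell, 19 genes were higher in the small tumor, 15 of them in the reported set. There Ifng was at -0.19 and Il2ra in large against small at 0.91.

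A minimum of 50 CPM, which tests fewer genes, gave 12 higher and 4 lower genes in the small tumor and 51 and 28 higher genes in the large tumor against lung and small tumor. With no minimum, which adds genes, these were 63, 40, 226 and 182. Without the heat shock cluster 5 genes were lower in the small tumor, and Hspa1b, a leading gene of that cluster, was at 0.76 in the small and 0.58 in the large tumor against the lung, and Klra4 at -0.044 in large against small. Without cells holding a cycling marker UMI (4328, 2360 and 50 cells left), 118 genes were lower in the large tumor than in the lung, 90 of them in the reported set. Ccr7 was at -0.10 and Cx3cr1 in large against small at -0.079.

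Isg15 in the large tumor against the lung was at 0.15 with mitochondrial UMIs at most 5% and at 0.14 with the mixed cluster included. The interferon median in large against small was 0.16 and 0.14 under those settings and 0.005 with doublets kept. The mitochondrial limit of 5% gave NK-like shares of 95.9%, 88.9% and 71.2% in lung, small and large tumor. Shares were 95.8% and 87.6% in lung and small tumor with doublets kept, 95.6% and 88.2% with 1000 UMIs and 500 genes, 94.2% in the lung with 200 UMIs and 100 genes, and 87.6% in the small tumor at resolution 1.0. The share of NK-like cells with a Cd27 UMI was 2.55% in the lung and 6.56% in the small tumor at 500 UMIs and 10.4% and 20.1% at 2000 UMIs. Unthinned it was 16.0%, 31.7% and 41.2% in lung, small and large tumor. These shares grow with depth by construction.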

Other observations

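The comparisons within the other cell classes of the small tumor and the non-tumoral lung were chosen after the data were seen. B cell-like cells of the small tumor (363 cells, against 86 in the lung) had higher type I interferon response genes, with a median log2 ratio of 1.27 over 14 members (member interval 0.65 to 1.89). Irf7, the regulator of interferon production, had a ratio of 3.97 (1.97 to 9.36), and Bst2, which tethers virus particles, of 3.49 (1.91 to 7.12). These cells also held more NK RNA in the lung than in the small tumor, with 1003.7 against 172 CPM of Gzma, so the RNA they carried from other cells differed. Cd83, first of the higher genes of at least 50 CPM in NK-like cells, had a ratio of 1.05 in B cell-like cells (0.924 to 1.20). Its level there, 831 against 792 CPM, was far above that in NK-like cells of either library.

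ILC1-like cells of the small tumor (207 cells, against 153 in the lung) had higher proliferation genes, with a median of 1.97 over 16 members (member interval 0.94 to 2.48), while the same list stood at -0.30 in NK-like cells. A Mki67 UMI was found in 9 of 207 and 1 of 153 of these cells before thinning, and an NK-like cluster led by cycling genes held 78 cells in the lung and 34 in the small tumor. Stmn1, a microtubule regulator of dividing cells, had a ratio of 5.25 (3.96 to 7.10), and Rrm2, a subunit of ribonucleotide reductase, of 19.8 from 77 and 2 UMIs. Gzmc, the granzyme C gene, had a ratio of 7.30 (4.97 to 11.1), Ly6a of 6.52 (3.85 to 11.9) and the chemokine gene Cxcl10 of 7.83 (4.56 to 14.6). In the same class Cd74 (4.82), H2-Ab1 (6.69) and H2-Aa (4.88), genes of antigen-presenting cells, were higher and Cd3g (0.204) was lower, and a different mixture of cells in the class was not excluded. Klf2 (0.376) and Klrg1 (0.198, from 5 and 13 UMIs) were lower. The interferon list stood at 0.79 (member interval 0.459 to 1.096).

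The heat shock gene Hspa1b was lower in the small tumor in each of these classes, while the member interval of the dissociation and heat shock list included 0 in each. The ratio of Hspa1b was 0.222 in B cell-like, 0.634 in ILC1-like and 0.425 in macrophage or monocyte-like cells, beside 0.506 in NK-like cells. Jun was at 0.258 in B cell-like cells, and at 0.833 in ILC1-like and 1.28 in macrophage or monocyte-like cells, where the intervals included 1. Cell barcodes shared between the small-tumor and non-tumoral libraries numbered 7, beside 5.97 expected by chance, and those shared between the large-tumor and small-tumor libraries numbered 1, beside 0.11 expected.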
